A study of Mus musculus with 6 samples.

How the data were processed

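RNA from F4/80+ cells of tumours implanted in wild type (3 samples) and St2-/- mice (3 samples) was hybridised to Affymetrix Gene 1.0 ST arrays, 1 array per sample, per the labels' protocols. The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and summarises probes by median polish. Its version and annotation are not given in the sources used here, nor is the log base, which was taken as log2 because RMA returns that scale and the values span the range usual for it. Values carried 2 decimals. Because quantile normalization gives arrays like distributions, a shift shared by most genes cannot be seen in these values.

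The table held 35556 probe sets. The platform annotation paired 21789 of them with 1 gene symbol and 1621 with several, and 12146 were not listed there and stayed unnamed. Only probe sets with 1 symbol entered the main test, and the probe set with the highest mean over the 6 arrays stood for a gene, which left 19938 genes. Of these, 999 had more than 1 probe set, and in 2 of them another called probe set went the opposite way. Of the gene identifiers, 21698 (99.6%) matched the mouse reference gene table (assembly GRCm38.p6), and 0 symbols were changed. That table was used for names and gene order only, since the platform's build is not given in the sources used here. The targeted gene had no probe set named for it, so neither its level nor the other settings listed for it were analysed here.

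St2-/- was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust prior, two-sided, Benjamini-Hochberg over all genes). Genes with an adjusted p under 0.05 were called higher or lower, with no filter on dim genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 37 lists of at least 5 measured members. The lists held 764 symbols, of which 695 were measured. The comparison, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except those said to have been added. The named genes are the 12 called genes with the greatest rise and the 12 with the greatest fall, up to 4 members of each list with the smallest p, and the members of both activation lists as counts. Genes with only a provisional, olfactory, vomeronasal or small RNA name were to be skipped, and 0 were.

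The alternatives to the main settings were centring each array on its median, cyclic loess, a variance prior with an intensity trend or robust to outlying variances, array weights, all rows of the table, the mean of all probe sets of a gene, leaving out the dimmest 40% of genes, the replicate number as a block, leaving out each array, a plain two-sample test per gene, camera with an estimated correlation, and fry. A limma test against a minimum fold of 1.5 and gene families defined by the letters of the symbol were added after seeing the data.

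The gene test was tested on simulated data of 19938 genes on 3 against 3 arrays, in 20 draws with 200 changed genes each. It recovered 13.6% of genes changed by 0.25 on the log2 scale, 95% at 0.5 and 100% at 1 and 2, and 5.54% of its calls were genes left unchanged. The real comparison called 4140 genes, so these shares need not hold for it. In a single further draw with 1 list shifted, 0 of 24 lists that share no member with it were called. The averaging over 20 draws and the leaving out of lists that share members were adopted after the result of a first single draw was seen. The simulated genes varied independently of one another, so this does not test the preset correlation of camera. The labels give no scan date or batch.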

Results

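Gene expression was measured in F4/80+ cells isolated from tumours that had been implanted in wild type or St2-/- mice. F4/80 is a surface protein of mouse macrophages, and ST2 is the receptor for the cytokine IL-33. The labels do not name the tumour. Each group held 3 samples, each hybridised to its own array, and the number of arrays limits the precision. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Values are the deposited RMA values on a log2 scale, and differences are given as St2-/- minus wild type. The median over the tested genes was 5.91, 5.88 and 5.93 in wild type replicates 1, 2 and 3, and 5.82, 5.82 and 5.81 in the St2-/- replicates. Pearson correlations over genes were 0.996 to 0.998 within groups and 0.986 to 0.988 between groups. The first principal component held 73.0% of the variance and separated the groups, and the second held 8.78%. The gene of ST2 had no probe set named for it in the platform table used, so its level was not analysed here and the genotypes were not checked against it.

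The comparison of St2-/- with wild type asked how loss of ST2 in the host was associated with gene expression in F4/80+ cells of the tumour. Genes known from alternatively activated macrophages and from fibroblast matrix were among those that fell most, and genes known from interferon responses and from NK, T and dendritic cells were among those that rose most. Cbr2, a carbonyl reductase (probe set 10393936), averaged 11.02 ± 0.05 (SD, n = 3) in wild type and 7.33 ± 0.09 (SD, n = 3) in St2-/-, a log2 difference of -3.70 ± 0.07 (SE). Arg1, the arginase of alternatively activated macrophages (probe set 10368343), averaged 11.66 ± 0.04 (SD, n = 3) and 8.48 ± 0.03 (SD, n = 3), a 9.02-fold lower level. Gbp2b, an interferon-inducible GTPase (probe set 10496555), averaged 5.67 ± 0.19 (SD, n = 3) in wild type and 9.26 ± 0.10 (SD, n = 3) in St2-/-, a 12.1-fold higher level. Il2ra, the alpha chain of the IL-2 receptor (probe set 10469278), averaged 5.23 ± 0.06 (SD, n = 3) and 8.80 ± 0.11 (SD, n = 3), an 11.8-fold higher level. Limma adjusted p-values were 6.13e-09 for Cbr2, 6.13e-09 for Arg1, 2.5e-08 for Gbp2b and 7.04e-09 for Il2ra.

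The other genes with the greatest rises were Dnase1l3, a secreted DNase (log2 difference 3.59), Klrk1, the NKG2D receptor of NK and T cells (3.38), Xcr1, a chemokine receptor of cross-presenting dendritic cells (3.37), the neuronal enolase Eno2 (3.18), Plac8 (3.18), Cyfip2 (2.65), Pianp (2.44), the Ly49 receptor gene Klra3 (2.40), the B cell attractant Cxcl13 (2.40) and the interferon-inducible chemokine Cxcl11 (2.38). The other genes with the greatest falls were the pseudogene Nlrp1c-ps (-3.69), the complement receptor Vsig4 (-3.61), the matrix proteoglycans Lum (-3.56), Dcn (-3.33), Ogn (-3.04) and Prelp (-2.94), the acute phase gene Saa3 (-3.27), the haemoglobin scavenger receptor Cd163 (-3.19), the arginine transporter Slc7a2 (-2.98) and Lcn2, a siderophore-binding protein of neutrophils and inflamed tissue (-2.90). Standard errors of these differences lay between 0.065 (Eno2 and Slc7a2) and 0.156 (Lum), and in each of these genes every array of one group lay beyond every array of the other. Gbp2b, Klra3, Nlrp1c-ps and Saa3 have near-identical relatives, and the probes of this platform may not tell them apart, so their values are uncertain.

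**Figure D1:**
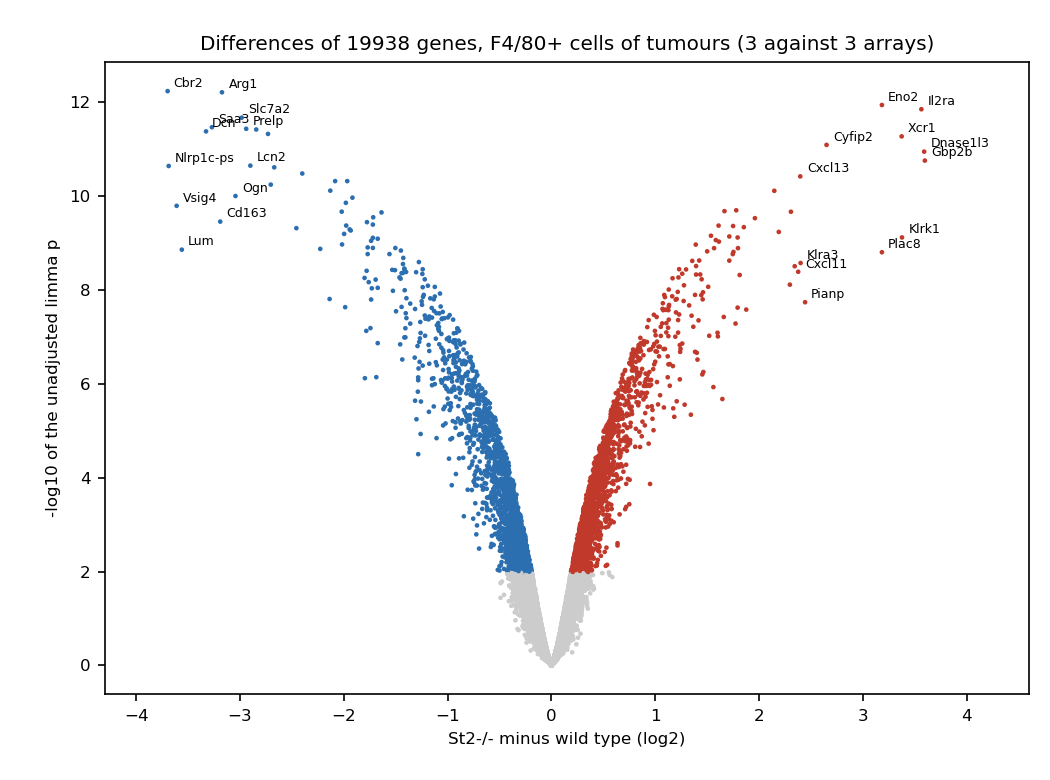
Volcano plot of the 19938 genes tested, with the log2 difference (St2-/- minus wild type) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; red points are higher and blue points lower at an adjusted p under 0.05, and grey points did not pass. Cbr2 lies farthest to the left at -3.70 and Gbp2b farthest to the right at 3.60.

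**Figure D2:**
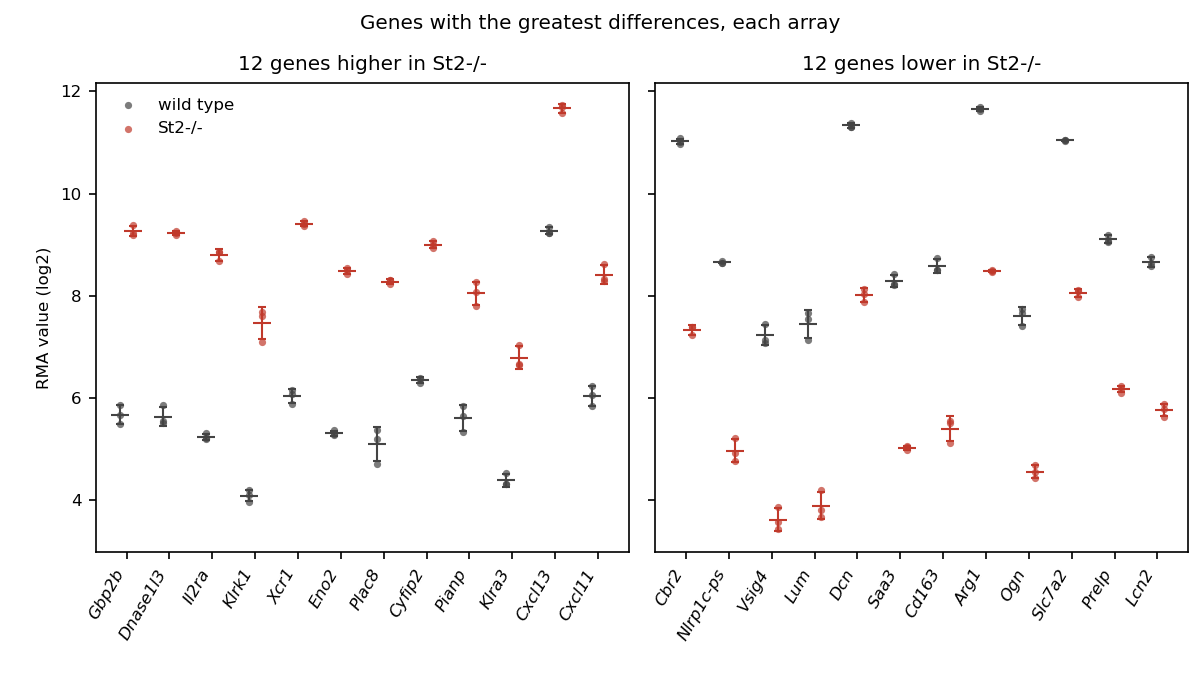
RMA values (log2) of the 12 genes with the greatest rise and the 12 with the greatest fall, with each array as a point and bars for the mean ± SD of 3 arrays (grey, wild type; red, St2-/-). The arrays of the groups do not overlap in any of these genes.

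Over all genes, 4140 of 19938 (20.8%) passed an adjusted p of 0.05 in limma, 2142 higher and 1998 lower in St2-/-, and 6571 had an unadjusted p under 0.05. A difference of at least 2-fold was found for 305 of them, 130 higher and 175 lower. The median size of a called log2 difference was 0.38 and the smallest was 0.19, against a median standard error of 0.0766. The groups did not overlap for 7254 genes (36.4%), where chance gives 10%. Calls were made for 6.39% of the dimmest 40% of genes and for 30.4% of the brighter genes. Higher calls were 51.7% of all calls, and 72.6% (3494 higher and 1320 lower) after each array was centred on its own median. The number of genes passing limma's test against a minimum fold of 1.5, chosen after seeing the data, was 361.

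Genes of alternative macrophage activation fell as a list. Of 30 measured members, 19 were lower, 3 higher and 8 not called, with a median log2 difference of -0.57 (camera adjusted p = 4.91e-10). The list had an adjusted p of 0.038 with an estimated correlation. Adjusted over the list alone, 22 members passed, 3 higher and 19 lower. Mrc1, the mannose receptor, fell from 11.28 ± 0.01 to 9.65 ± 0.02 (SD, n = 3), a difference of -1.64, and Folr2, a folate receptor of resident-type macrophages, differed by -2.84. Arg1 and Cd163 are further members. Of the 30 members 16 also stand in other lists. The classical activation list rose with a median of 0.17 (camera adjusted p = 0.00226), with 12 members higher, 6 lower and 8 not called of 26, and adjusted over the list alone 12 higher and 6 lower. With an estimated correlation its adjusted p was 0.0661. Its members moved apart: the chemokine Ccl5 (1.54), Cxcl11 and Nos2, the inducible nitric oxide synthase (1.38), rose, and Slc7a2, which supplies arginine to cells, fell (-2.98).

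**Figure D3:**
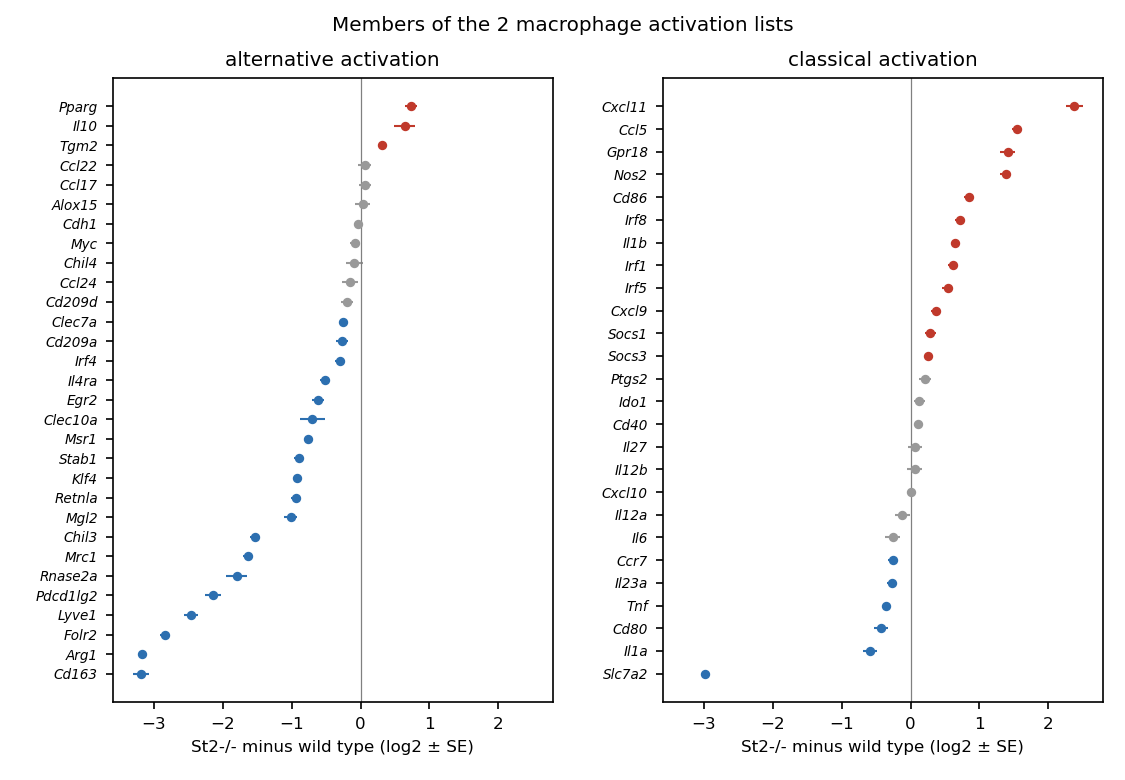
Log2 difference (St2-/- minus wild type) ± SE of each measured member of the alternative activation list (30 genes, left) and the classical activation list (26 genes, right); red members are called higher, blue lower and grey not called. In the alternative activation list 19 members are blue and 3 red, and in the classical activation list 12 are red and 6 blue.

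Interferon-inducible genes and antigen presentation genes rose. All 27 measured members of the type I interferon list were called higher, with a median of 0.65 (camera adjusted p = 1.94e-24), also adjusted over the list alone. The list's adjusted p was 0.038 with an estimated correlation. Oas3, an antiviral RNA sensor enzyme, rose from 6.92 ± 0.08 to 8.31 ± 0.02 (SD, n = 3), a difference of 1.39. The antiviral gene Rsad2 rose by 1.08, the transcription factor gene Irf7 by 1.13 and the ISG15 protease gene Usp18 by 1.20. Of 10 measured MHC class II genes 8 were higher and 2 not called (median 0.61, camera adjusted p = 6.29e-09). Adjusted over the list alone 8 were higher, and the list's adjusted p was 0.038 with an estimated correlation. The higher genes included H2-Eb1 (0.84), H2-Ab1 (0.65) and Ciita, the master regulator of class II transcription (1.02). Of 12 measured MHC class I genes 11 were higher and 1 not called (median 0.58, camera adjusted p = 3.81e-10, and 11 higher adjusted over the list alone), among them the peptide transporter gene Tap1 (0.88) and the immunoproteasome gene Psmb9 (0.81). With an estimated correlation the class I list had an adjusted p of 0.0577. The H2 genes share sequence with one another, so their separate values are uncertain.

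Cell cycle and energy metabolism lists were higher in camera with its preset correlation. Of 37 measured cell cycle genes 20 were higher, 1 lower and 16 not called (median 0.24, camera adjusted p = 5.22e-10), and adjusted over the list alone 28 were higher and 1 lower. The list's adjusted p was 0.0577 with an estimated correlation. The mitotic checkpoint kinase genes Bub1 and Bub1b rose by 0.62 and 0.57. Of 27 hypoxia and glycolysis genes 12 were higher, 3 lower and 12 not called (median 0.18, camera adjusted p = 0.00226, and 14 higher and 4 lower adjusted over the list alone). Their adjusted p was 0.392 with an estimated correlation and 0.174 after cyclic loess. Pfkfb3 and the hexokinase gene Hk2 rose by 0.99 and 0.68, and Car9, a carbonic anhydrase induced by hypoxia, fell (-1.08). Of 31 oxidative phosphorylation genes 4 were higher and 27 not called (median 0.11, camera adjusted p = 0.00225, and 4 higher adjusted over the list alone). That adjusted p was 0.389 with an estimated correlation and 0.292 after cyclic loess.

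Lists of matrix, vessel and immediate early genes fell in camera with its preset correlation. Fibroblast and pericyte markers had 14 members lower, 1 higher and 10 not called of 25 (median -0.61, camera adjusted p = 4.91e-10). Adjusted over the list alone 15 were lower and 2 higher, and the adjusted p was 0.038 with an estimated correlation. Next to Dcn and Lum, the matrix genes Bgn and Sparc fell (-1.98 and -1.43). Endothelial markers had 17 members lower, 3 higher and 3 not called of 23 (median -0.43, camera adjusted p = 3.07e-07). Adjusted over the list alone 17 were lower and 3 higher, and the adjusted p was 0.038 with an estimated correlation. Lyve1, which resident-type macrophages also express, fell (-2.46), as did the VEGF receptor gene Flt1 (-2.02) and Vwf (-1.13), and the VEGF receptor gene Kdr rose (1.52). Angiogenic factors had 13 members lower, 3 higher and 8 not called of 24 (median -0.39, camera adjusted p = 1.17e-05, and 15 lower and 3 higher adjusted over the list alone). The adjusted p was 0.0984 with an estimated correlation. Angpt1 and Igf1 fell (-2.08 and -1.72), and Hgf (0.88), Vegfa (0.60) and Adm (0.41), named after their values were seen, were the 3 members called higher. Matrix proteases and their inhibitors had 12 members lower, 5 higher and 8 not called of 25 (median -0.33, camera adjusted p = 0.00996, and 13 lower and 6 higher adjusted over the list alone). The adjusted p of this list was 0.143 with an estimated correlation. The inhibitor genes Serpinb2 (-2.23) and Timp2 (-1.45) and the protease gene Adamts1 (-1.53) fell, and the protease gene Mmp25 rose (1.40). Immediate early and heat shock genes, which dissociation of tissue can induce, had 14 members lower, 3 higher and 8 not called of 25 (median -0.42, camera adjusted p = 3.75e-06, and 16 lower and 3 higher adjusted over the list alone). The adjusted p was 0.0688 with an estimated correlation. The immediate early genes Fosb, Ier2, Egr1 and Klf2 fell by 1.12, 0.91, 0.78 and 0.78 on the log2 scale. No heat shock gene of the list was called lower: Hsph1 (0.60) and Hspb1 (0.53), named after their values were seen, were called higher, and the others were not called. Hspb1 lost its call without wild type replicate 1 or 3 or St2-/- replicate 1 or 2 (limma adjusted p from 0.0715 to 0.0768) and in a plain two-sample test (0.166).

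**Figure D4:**
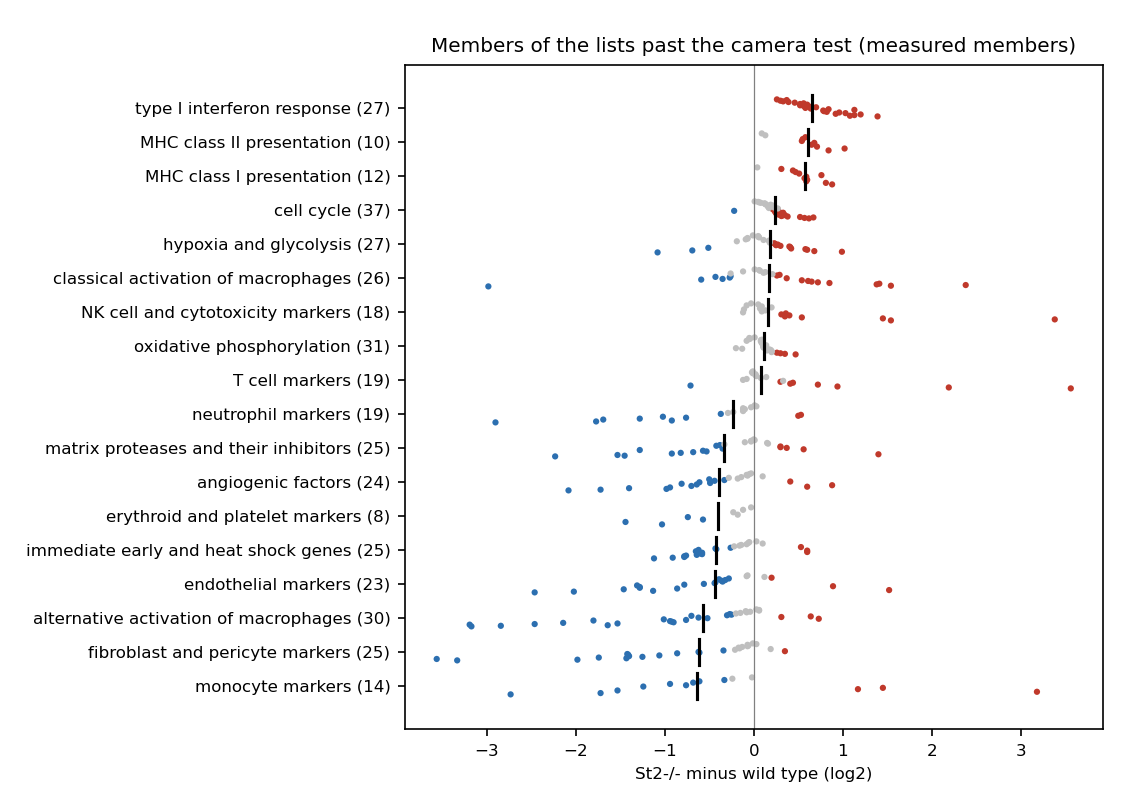
Log2 differences (St2-/- minus wild type) of the measured members of the 18 lists past the camera test, with 1 point per gene, the number of measured members in parentheses and a black bar at the median; red members are called higher, blue lower and grey not called. The medians run from -0.64 (monocyte markers) to 0.65 (type I interferon response).

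Markers of other blood cells moved with genotype in camera with its preset correlation. Monocyte markers had 9 members lower, 3 higher and 2 not called of 14 (median -0.64, camera adjusted p = 0.000575, and 10 lower and 3 higher adjusted over the list alone). With an estimated correlation the adjusted p was 0.0661. F13a1 (-2.73) and Fn1 (-1.72) fell and Plac8 rose. Neutrophil markers had 8 lower, 2 higher and 9 not called of 19 (median -0.23, camera adjusted p = 0.000174, and 10 lower and 2 higher adjusted over the list alone), with S100a8 (-1.77) and S100a9 (-1.69) beside Lcn2. Their adjusted p was 0.0577 with an estimated correlation. Erythroid and platelet markers had 4 lower and 4 not called of 8 (median -0.40, camera adjusted p = 0.00029, and 6 lower adjusted over the list alone), with the platelet chemokine genes Pf4 (-1.03) and Ppbp (-1.44) among them. This list too had an adjusted p of 0.0577 with an estimated correlation. NK cell and cytotoxicity markers had 8 higher and 10 not called of 18 (median 0.16, camera adjusted p = 0.000158, and 8 higher adjusted over the list alone). Their adjusted p with an estimated correlation was 0.0577. Nkg7 (1.45) and Ifng (0.54; adjusted p = 0.0542 in a plain two-sample test without limma's moderation) rose beside Klrk1. T cell markers had 7 higher, 1 lower and 11 not called of 19 (median 0.08, camera adjusted p = 0.00226, and 8 higher and 1 lower adjusted over the list alone). The adjusted p of T cell markers was 0.183 with an estimated correlation and 0.0624 when dim genes were left out. Cd4 (2.19) and Cd3g (0.94) rose and Cd28 fell (-0.71).

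The macrophage marker list itself did not pass the camera test (adjusted p = 0.974), with 4 members higher, 4 lower and 9 not called of 17. The phagocytic receptor genes Mertk and Msr1 and the lysozyme gene Lyz2 fell (-0.72, -0.76 and -0.71) and Aif1 rose (0.59). Chosen after their values were seen, Csf1r, Cd68 and Adgre1 (the gene of F4/80) differed by 0.05 ± 0.06, -0.04 ± 0.06 and 0.31 ± 0.06 (SE), and of these Adgre1 was called. In the IL-33 receptor axis list, which did not pass either (adjusted p = 0.974, 2 higher, 2 lower and 12 not called of 16), Il33 fell from 8.38 ± 0.13 to 6.44 ± 0.04 (SD, n = 3), a 3.82-fold lower level (limma adjusted p = 2.39e-07). The kinase genes Irak2 and Irak3 rose by 0.85 and 0.62. Gata3 fell by 0.27 on the log2 scale, but its limma adjusted p was 0.0989 with arrays centred on their median, 0.126 after cyclic loess, and 0.051 to 0.107 without any of the arrays other than St2-/- replicate 2. Dendritic cell markers (adjusted p = 0.264) had 5 higher, 4 lower and 9 not called of 18, with Xcr1, the integrin gene Itgax (1.80) and the dendritic cell receptor gene Clec9a (1.88) higher and Fscn1 lower (-0.58). Of 31 CC and CXC chemokines (adjusted p = 0.387) 5 were higher, 9 lower and 17 not called, and Cxcl5 (-2.67) and Ccl9 (-1.28) fell. Neighbours of the targeted gene on chromosome 1 had an adjusted p of 0.336, with 4 higher, 3 lower and 18 not called of 25, among them Tbc1d8 (0.98) and Il1rl2 (-1.29).

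The remaining 14 lists did not pass. Camera adjusted p-values were 0.162 for NF-kB target genes, 0.228 for complement and phagocytosis genes, epithelial and tumour cell markers, and mast cell and basophil markers, 0.24 for B cell and plasma cell markers, and 0.264 for lipid handling genes, eosinophil markers and sex-linked genes. They were 0.368 for skeletal muscle and fat markers, 0.446 for cholesterol synthesis, 0.498 for chemokine and cytokine receptors, 0.532 for group 2 innate lymphoid cell markers, 0.605 for TGF-beta response genes and 0.779 for checkpoint ligands and suppressor genes. Lipid handling genes had 0.037, lower, after cyclic loess, and epithelial and tumour cell markers 0.046, lower, when dim genes were left out. In some of the 14 lists single members were called in both directions, and in others in 1 direction only. Lipid handling had 11 members lower and 5 higher, with the scavenger receptor gene Cd36 higher (1.57) and the lipid transfer gene Pltp (-1.07) and the desaturase gene Scd2 (-0.66) lower. Complement and phagocytosis had 8 higher and 6 lower, with the complement gene Cfb (1.58) and the Fc receptor gene Fcgr4 (1.39) higher. TGF-beta response genes had 3 higher and 6 lower, with Tgfb3 (1.05) higher and Ltbp3 (-0.54) and Ccn2 (-0.51) lower. The median, mean and camera direction differed in sign for the checkpoint, dendritic cell, B cell, receptor, group 2 innate lymphoid, macrophage and IL-33 lists. In all, 18 of 37 lists passed camera with its preset correlation, 9 higher and 9 lower. Of these, 5 held with an estimated correlation, each at an adjusted p of 0.038. They were the type I interferon, alternative activation, fibroblast and pericyte, MHC class II and endothelial lists. Camera with the preset correlation also called up to 10 lists when the 6 arrays were split in ways that mix the genotypes.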

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

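All tests of explanations below were chosen after the results were seen. Probe sets outside the comparison of named genes also differed between the genotypes in limma: 1026 of those that the platform annotation does not list (8.45%; 411 higher and 615 lower, 87 by at least 2-fold) and 387 of those it pairs with several genes (23.9%, 13 by at least 2-fold). They carry no single gene name here.

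A few genes known from dendritic, T and NK cells rose strongly within cells sorted for F4/80: Xcr1, Clec9a, Itgax, Cd4, Il2ra and Klrk1. If carried-over cells of these types were the cause, their other markers would rise about as far. This holds only for markers measured above background that all such cells share and macrophages lack, and the lists were not limited to these. The 15 other dendritic cell markers had a median log2 difference of -0.05 (SD 0.29; 2 higher and 4 lower), against 1.80 for the smallest change of Xcr1, Clec9a and Itgax. The 17 other T cell markers had 0.03 (SD 0.37; 5 higher and 1 lower), against 2.19 for Cd4, and the 17 other NK markers 0.13 (SD 0.49; 7 higher and 0 lower), against 3.38 for Klrk1. Of the other members of each list, 0 reached that change. The 6 genes were chosen for their large rises, so this count was fixed by the choice and is no evidence. The choice also lowers the medians of the other members. These medians argue only against carry-over that raised the markers of a type alike by that size. Carry-over that shows in some markers stays open, as does expression in F4/80+ cells themselves (not tested). Some carry-over of NK or T cells also stays open for the smaller, mostly one-sided rises such as Nkg7 (1.45) and Cd3g (0.94). So does carry-over of only the dendritic subset that Xcr1 and Clec9a both mark. Batf3 and Irf8, further genes of that subset named after their values were seen, do not decide it. Batf3 differed by -0.09 ± 0.08 (SE), and Irf8, also a member of the classical activation list, was called higher (0.72 ± 0.07, SE).

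Fibroblast and endothelial marker lists fell, which a smaller share of such cells in the St2-/- sort could give. Markers counted as measurable had a wild type mean above 5.26, the upper bound of the dimmest 40% of genes. Markers bright only in St2-/- were thus left out, which favours falls, though the full lists also had 1 and 3 members called higher. The 19 measurable fibroblast and pericyte markers spread with an SD of 1.09 (from -3.56 to 0.35, median standard error 0.077), 13 lower and 1, Col1a2, higher. The 17 measurable endothelial markers spread with an SD of 0.97 (from -2.46 to 1.52, median standard error 0.080), 14 lower and 3, Kdr, Pecam1 and Eng, higher; Col1a2, Pecam1 and Eng were named after their values were seen, and Eng lost its call after cyclic loess (limma adjusted p = 0.146) and without any single array (0.0539 to 0.122). This spread does not decide, since markers that macrophages or tumour cells also express, or that lie near background, would fall by less even if all cells of a type were lost alike. A smaller share of these cells and lower expression in the sorted cells cannot be told apart here.

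Several of the greatest changes lie in gene families that vary between mouse strains, such as Klra3 and Klrk1 on chromosome 6, so that a chromosome segment of another strain is a candidate explanation. Called genes of at least 2-fold were counted in windows of neighbouring genes on chromosome 6 and set against 10000 shuffles of the gene order. This was run in 12 versions (4 window sizes from 20 to 200 genes, 3 ways of counting related genes), with sizes and counting chosen while results were in view: p ran from 2e-04 to 1, with 5 of 12 under 0.05, so the outcome depends on the version. The densest window of 200 genes, with all genes counted, held Eno2, Pianp, Klra3, Klrk1, Cd4, Clec9a, Cd163 and Vwf among others. Several genes named above for cell types or macrophage activation are therefore also candidates for such a segment. Chromosome 5, with its chemokine and Gbp clusters, gave 6 of 12 (1e-04, the smallest 10000 shuffles can give, to 0.53). Windows of 100 and 200 genes there also passed with each symbol family counted once. They held genes outside those clusters, such as Anxa3, Hpse and Sparcl1. Whether clusters of immune genes or a strain segment gave the density on chromosome 5 was not tested, so it does not decide between these for chromosome 6. Chromosome 11, where Nlrp1c-ps lies, gave 1 of 12 (0.047 to 1), in a window that did not hold Nlrp1c-ps. Of 25 neighbours of the targeted gene 7 were called (28% against 20.8% of all genes, one-sided exact hypergeometric test, p = 0.25), and a strain segment cannot be told apart from a genotype effect for these genes, since the labels give no strain background.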

How the results depend on the processing

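The fold test and gene families were chosen after seeing the data. None of the genes with the greatest changes turned or lost its call in 408 comparisons. Of 169 genes followed, none turned with a call; of the 150 called, 15 lost the call in at least 1 setting other than the fold test, Gata3, Eng, Ifng and Hspb1 among them, and 63 under the fold test. The count of 4140 genes ran from 2887 to 3852 when each array was left out. With each array centred on its median 3494 genes were higher and 1320 lower. The plain two-sample test gave 2703 genes, 1222 of them lower, and the test against a minimum fold of 1.5 gave 361, 153 higher and 208 lower. The replicate numbers did not pair the samples (correlations of same-numbered deviations from -0.05 to 0.01); with the replicate block 3571 genes were called, 3437 of them also without it. Lists passing were 5 with an estimated correlation and 31 with fry, which does not compare a list with other genes. With an estimated correlation the adjusted p of MHC class I genes was 0.0577 and of classical activation 0.0661. The checkpoint list turned from higher to lower with fry (0.000969). Of the list comparisons, 557 kept side and direction, 16 lost and 14 gained a call. The cause of these changes was not tested, except that the fold test asks for a larger difference. Signal near background limits dim genes. The robust prior, plain and minimum-fold tests were not run for lists.

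In all 10 splits of the 6 arrays into 3 and 3, counting the real one, 1 split gave as many genes as the real 4140 (highest other 0) and 1 gave as many lists as the real 18 (highest other 10). The splits are too few for a share under 0.05. Each other split also mixes the genotypes, which adds their difference to the spread within groups and leaves part of it between groups. Its counts are therefore not those expected without a genotype difference.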

Other observations

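The gene families here were defined by the letters of the symbol, and their test chosen, after the data were seen. In all, 30 of 303 families passed with camera's preset correlation. With an estimated correlation camera called 0 of the 303 (20 at unadjusted p under 0.05, lowest adjusted p 0.534). Guanylate-binding proteins, interferon-inducible GTPases that act against intracellular pathogens, had all 8 measured Gbp genes higher, with a median log2 difference of 0.95 (camera adjusted p = 2.18e-10). With an estimated correlation the adjusted p of the family was 0.534. Gbp4 and Gbp8 rose by 1.78 and 1.77 and Gbp5 by 0.99, next to Gbp2b. Schlafen genes, many of them induced by interferon, had 8 of 9 members higher (median 0.58, camera adjusted p = 5.55e-08, and adjusted p = 0.534 with an estimated correlation), counting a pseudogene and an antisense gene, with Slfn1 (1.46) and Slfn4 (1.12) among them. Genes with symbols beginning with Tnfsf, a part of the TNF superfamily ligands, had 7 of 9 members higher (median 0.58, camera adjusted p = 0.000183). The adjusted p of this set was 0.59 with an estimated correlation. Tnf itself, a ligand outside this set, was called lower (-0.35). Tnfsf13b, the B cell survival factor BAFF, rose by 1.36, Tnfsf10, the death ligand TRAIL, by 1.21 and Tnfsf15 by 1.04. Members of the Gbp and Slfn families share sequence, so their single values are uncertain.

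Among the 30 were 3 sets that are described here by symbol letters alone because the letters can mix classes of proteins. Symbols beginning with Ddx had 14 genes higher and 1 lower of 35 (median 0.18, camera adjusted p = 0.000123, and adjusted p = 0.637 with an estimated correlation). Symbols beginning with Eif had 16 higher of 49 (median 0.13, camera adjusted p = 0.000123, and adjusted p = 0.644 with an estimated correlation). Those with Rps had 15 higher of 31 (median 0.19, camera adjusted p = 0.000123, and adjusted p = 0.585 with an estimated correlation).

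Collagen genes had 15 members lower and 2 higher of 44 (median -0.18, camera adjusted p = 1e-04, and adjusted p = 0.644 with an estimated correlation). Adamts protease genes had 6 lower of 18 (median -0.27, camera adjusted p = 0.00111, and adjusted p = 0.614 with an estimated correlation).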
